A study of Arabidopsis thaliana with 10 samples.

How the data were processed

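Uncapped and cleaved polyadenylated RNAs of Arabidopsis thaliana shoots were measured by GMUCT 2.0, an RNA sequencing method that captures RNAs with a free 5′ monophosphate, so that the first base of each read is the position where an RNA was cut or decapped. The 10 libraries are 3 of shoot apices, 1 of cotyledons and 6 of expanded leaves. Per the labels' protocols, tissue was flash frozen and RNA was extracted with Trizol. The deposited file of each library lists distinct read sequences with the count of reads for each, and these deposited counts were not normalized. Per the submitters' processing notes the genome build was TAIR9. The aligner and any trimming or filtering before deposit are not given in the sources used here, and no coordinates were taken from the submitters.

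All sequences were placed anew on the TAIR10.1 assembly, whose chromosomes 1 to 5 have 30427671, 19698289, 23459830, 18585056 and 26975502 bases, with bwa 0.7.19. Each read had to match end to end with at most 1 mismatch, first on the genome and then on spliced transcripts, and the better placement was kept. The 5′ ends of reads with a single best position on the sense strand of a nuclear gene were counted. Reads with several equally good positions were left out, so genes with near-identical copies, such as the chlorophyll a/b-binding CAB2 and CAB3 or the Rubisco small subunits RBCS1B and RBCS2B, are represented only by their distinguishing stretches and their values are uncertain. Positions in exons of more than 1 gene on the same strand were also left out. Between 6.20% and 9.35% of reads per library found no place. Ribosomal, transfer and other non-coding RNA genes outside the tested gene types were not tested.

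Total reads ran from 6239501 to 29308413 per library, and reads in tested genes from 5082212 to 24358955. A floor of 3 counts corresponds to 0.114 to 0.699 CPM (gene counts scaled by library size and the TMM factors of edgeR), depending on the library. Intervals and floors cover counting error only, because the deposited files hold no molecular identifiers. Reads at single positions are given as RPM, scaled by the reads in genes of a library without TMM factors, while fold changes at those positions come from the fitted model.

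Groups came from the labels. No library has a replicate of its own condition: the apex and leaf groups pool libraries of different age, leaf number and genotype, and nothing in the labels says whether a library came from 1 or several plants. P-values therefore measure only the spread between these samples. Apices were compared with leaves over 9 libraries. FLC and flc-3 plants were compared in 3 pairs matched by organ and leaf number (apex at day 11, leaf 9, leaf 11), with the pair as a block. Late leaves (9 and 11) were compared with early leaves (1 and 2 pooled, and 3), with genotype as a covariate. Both early libraries are from flc-3 plants, so the folds of that model rest on 2 late against 2 early flc-3 leaves, and the FLC leaves add only 1 residual degree of freedom. The groups, tests, gene lists, rule for named genes and main alternatives were fixed before the data were examined.

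Genes with at least 1 CPM in at least 3 of the fitted libraries were tested with edgeR 4.0.16 (robust quasi-likelihood, two-sided) in R 4.3.3, with a Benjamini-Hochberg threshold of 0.05. Residual degrees of freedom were 7 for apices against leaves, 2 for genotypes and 3 for leaf position. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. The lists were cell cycle and DNA replication, cytosolic ribosomal proteins, meristem and boundary regulators, light harvesting and photosystems, Rubisco and Calvin cycle, salicylic acid and defence, senescence, flowering time and floral transition, small RNA and RNA decay machinery, and as markers of other cell types floral organ identity, stomatal lineage, trichome and epidermis, and vascular. The ribosomal list was defined by gene symbols or product names. From it, 16 symbols that named plastid or mitochondrial ribosomal proteins or resistance proteins were removed after the data had been seen, which left 29 members.

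For cleavage sites, 63 mature microRNA and tasiRNA sequences of 46 families, written down from general knowledge because no sequence database was used, were matched to transcripts. Sites scored at most 4 (mismatch 1, G:U pair 0.5, both doubled from microRNA position 2 to 13). A site counted as found when at least 5 reads began between the bases opposite microRNA positions 10 and 11 and this was the highest position within 50 bases on each side, in at least 2 libraries. The same search was run with 100 sets of shuffled sequences. The 99 known targets were also listed from general knowledge. Counts at found sites with at least 10 reads were tested with edgeR, using the library sizes and TMM factors of the genes, and once more relative to the remaining reads of the same gene. Reads at the sites of the SPL genes (miR156 and miR157) and of the AP2-like genes (miR172) were summed per library and compared by exact two-sided permutation tests on the log2 scale, so their folds are ratios of geometric means.

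Named genes were FLC, the 8 largest fold changes in each direction among genes past the threshold with a mean of at least 10 CPM and no overlap between groups (for genotypes, the same direction in all 3 pairs), and up to 4 tested members of each list with the smallest p. Named sites were up to 3 known targets per family with the smallest p, the 10 known sites with most reads and up to 6 found sites outside the known targets. A fold against a group with 0 reads is a lower bound against 3 counts over the whole group. Against a group with 1 to 3 reads, the ratio is given with its exact 95% counting interval.

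Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, counts without the highest position of each gene, other sets of libraries and covariates, leaving out each library or pair, other site rules, and, added after the data had been seen, reads without a mismatch. The share of 5′ ends per codon position and before stop codons was computed from 27422 transcripts. This was first run with 15 codons left out at each end, which departed from the plan, and then as planned. Both sets of codon shares are given.

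The steps were tested on simulated data. Of genes changed 4-fold and 8-fold, the gene test recovered 31 of 48 and 44 of 49 for apices against leaves (18176 genes, 2 unchanged genes called), 45 of 50 and 50 of 50 for genotypes (17182 genes, 15 called) and 32 of 50 and 45 of 48 for leaf position (16940 genes, 7 called). At 2-fold it recovered 3 of 49, 5 of 50 and 3 of 49, and at 1.5-fold none in any of these 3 comparisons. Only 200 genes were changed in each simulation, so this does not give the limit for the apex and leaf data. There 10197 genes passed and 8124 of them changed at least 2-fold, so smaller changes were called too. All 7 calls for genotypes and all 102 for leaf position were at least 2-fold. Of 20 sites changed 4-fold, 14 were recovered for apices against leaves, 4 for genotypes and 2 for leaf position, with 1, 0 and 0 unchanged sites called. The site search found 44 of 50 simulated cuts at 5 reads per library and 50 of 50 at 20, and of the 399 sites searched, none without a cut was found. The simulated background was even along each transcript, without the peaks of real reads, so these counts do not measure the error of the search in the data. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.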

Results

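GMUCT 2.0 was applied to shoots of Arabidopsis plants of the Col-0 background that carried a FRI allele from the accession Sf-2. FRI activates FLC, a MADS-box repressor of flowering, and the plants had either a working FLC gene (here called FLC plants) or the flc-3 mutation. Apices with leaf primordia were taken from FLC plants on day 11 and from flc-3 plants on days 9 and 11. Cotyledons came from FLC plants on day 6. Expanded leaves were leaf 9 and leaf 11 of FLC plants on day 33 and, from flc-3 plants, leaves 1 and 2 on day 14, leaf 3 on day 23, and leaves 9 and 11 on day 32. Leaf 11 was a rosette leaf in FLC plants and a cauline leaf in flc-3 plants. In the order FLC apex, flc-3 apices of days 9 and 11, cotyledons, FLC leaves 9 and 11, flc-3 leaves 1 and 2, 3, 9 and 11, the libraries held 15560899, 20168275, 27238823, 13184393, 11665847, 6239501, 8093985, 16964093, 24760111 and 29308413 reads. Counts per gene measure 5′ ends of decaying and cleaved RNA, not the level of intact transcripts.

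FLC, the gene mutated in flc-3 (AT5G10140, TAIR10.1 chromosome 5, 3173382 to 3179448), stood at 79.9 CPM in the FLC apex, 76.7 in FLC leaf 9, 75.5 in FLC leaf 11 and 35.9 in the cotyledons. In flc-3 plants it stood at 9.16 and 10.8 CPM in the apices of days 9 and 11 and at 5.98, 10.2, 11.8 and 5.14 in leaves 1 and 2, 3, 9 and 11. The 4 FLC libraries thus lay above the 6 flc-3 libraries without overlap. Which part of the gene flc-3 lacks is not given in the sources used here, so this checks the labels only by level.

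The first question was which RNAs are cut by microRNAs in these shoots. A microRNA directs a cut of its target between the bases opposite its positions 10 and 11, which leaves a peak of 5′ ends at 1 position. Most reads were found at AFB3, an auxin receptor F-box protein gene and target of miR393, where 26022 reads over the 10 libraries, 59.6% of the reads of the gene, began inside GAAACAATGCGATCCCTTTGGA (chromosome 1, 4369085 to 4369106, coding sequence of exon 4 of 4). TOE2, an AP2-like repressor of flowering and target of miR172, had 12624 reads (61.0%) inside ATGCAGCATCATCAGGATTCT (chromosome 5, 24210889 to 24210909, coding, exon 9 of 10). NAC1, a NAC transcription factor gene and target of miR164, had 10940 reads (76.4%) inside AGCACGTACCCTGCTTCTCCA (chromosome 1, 20947142 to 20947162, coding, exon 3 of 3). HAM2, a GRAS gene that maintains meristems, had 4994 reads (61.6%) at the miR171b position of its only exon (chromosome 3, 22411547 to 22411567). Its relative HAM1 (chromosome 2, 18619128 to 18619151) had a pair of peaks 3 bases apart, with 2731 reads at the position of miR171a and 2571 at that of miR171b. The other sites with most reads were TOE1 with 3047 at the miR172c position, AFB2 with 1219 (miR393a), SPL3 with 1209 in its 3′ UTR (miR156a, chromosome 2, 14305878 to 14305897) and AGO1 with 1052 (miR168a).

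**Figure D1:**
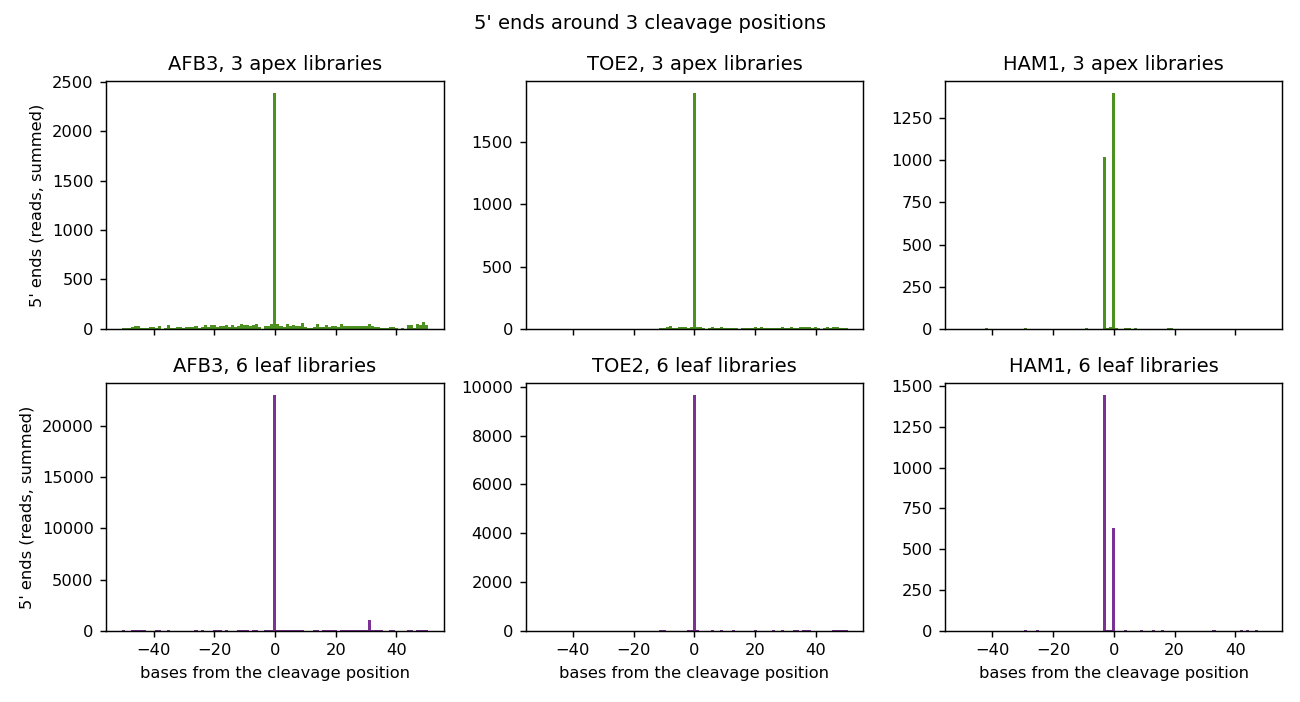
Reads beginning at each base (vertical axis, reads) from 50 bases before to 50 bases after the expected cut at AFB3, TOE2 and HAM1. The horizontal axis counts bases along the genome, any intron included. At TOE2 no read began 50 to 12 bases before the cut. Reads are summed over the 3 apex and over the 6 leaf libraries. The highest peak of AFB3 and TOE2 is at the expected cut, and HAM1 shows a peak at the miR171a position and another 3 bases upstream, at the miR171b position.

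Of 99 known targets, 80 had a predicted site and could be searched. Cuts were found at 50 of these 80, and in all 10 libraries at 19. Of the known targets of each family, they covered 8 of 11 SPL targets of miR156 and miR157, 6 of 6 AP2-like targets of miR172, 4 of 5 targets of miR393, 4 of 5 class III homeodomain targets of miR165 and miR166, 5 of 7 NF-YA targets of miR169, 3 of 3 auxin response factors of miR160, 3 of 3 HAM genes of miR171 and 3 of 6 targets of miR164. Targets were also found for miR159 (2 of 8), miR319 (3 of 5), miR173 (3 of 4), the tasiRNAs directed at ARF genes (2 of 3), and miR167, miR168, miR403 and miR824 (1 target each). No cut was found at the predicted sites of miR394, miR395, miR397, miR399, miR408, miR827, miR828 and miR2111. Of the SPL targets, SPL13A and SPL13B had no read at the miR156a or miR157a position in any library. Reads with several equally good positions were left out, so cuts in near-identical gene copies could not be seen. No site within the score limit was predicted in the 7 targets listed for miR396, the 3 for miR398, or in TAS3 (miR390) and DCL1 (miR162). The same held for ORE1 (miR164), ARF6 (miR167), MYB81 (miR159), TAS1B (miR173) and LAC3, LAC12 and LAC13 (miR408). These 19 targets were not tested. In all, 75 of 399 predicted sites were found, 58 of them in known targets, and 48 when at least 5 libraries were required. Shuffled sequences gave a mean of 0.04 and at most 1 site per set over 100 sets (one-sided permutation p = 0.0099, the smallest that 100 sets can give).

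Sites outside the listed targets numbered 17. NG1 (AT1G62720), a pentatricopeptide repeat gene, was cut at the miR400 position in 10 libraries (154 reads in all, chromosome 1, 23228516 to 23228536, exon 1 of 1). AGO3, an Argonaute gene, was cut at the miR403 position of its 3′ UTR in 8 libraries (105 reads, chromosome 1, 11192399 to 11192419). AT3G12977, which belongs to the NAC family, was cut at the miR164a position in 7 libraries (115 reads, chromosome 3, 4145631 to 4145651), and AT2G34010 at the miR159a position in 7 (98 reads, chromosome 2, 14369392 to 14369412). AT3G16710 (miR400, 58 reads, chromosome 3, 5691004 to 5691024) and AT1G63150 (miR161.2, 45 reads, chromosome 1, 23420381 to 23420401) were each cut in 5 libraries.

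Cleavage in apices was then set against that in expanded leaves. All apices came from days 9 and 11 and all leaves from days 14 to 33. Organ and plant age therefore cannot be separated in any comparison of apices with leaves. The miR393 sites of the auxin receptor genes TIR1, AFB3 and AFB2 carried fewer cut ends in apices, while that of AFB1 did not pass (log2 -0.93 ± 0.60 SE, adjusted p = 0.236). TIR1 had 0.279 ± 0.129 RPM (site reads scaled to the reads in genes, SD, n = 3 apices) against 6.38 ± 4.33 (n = 6 leaves), 29.2-fold lower (log2 -4.87 ± 0.82 SE, edgeR adjusted p = 2.66e-04). AFB3 had 46.4 ± 16.8 against 269 ± 138, 7.47-fold lower (adjusted p = 0.00183). TOE2 was 3.76-fold lower, at 36.5 ± 8.49 against 109 ± 35.5 RPM (adjusted p = 0.00206). These changes exceeded those of the genes' other reads: relative to them the log2 change was -5.07 at TIR1 (adjusted p = 7.87e-07), -2.26 at AFB3 (3.28e-05) and -2.39 at TOE2 (3.28e-05). AFB2 (4.97-fold, adjusted p = 0.00427) and the miR157a site of SPL11, a gene of the squamosa promoter binding family (9.62-fold, adjusted p = 2.66e-04), were lower too. NAC1 cut ends were 85.4-fold lower in apices (1.66 ± 0.741 against 112 ± 49.3, adjusted p = 6.66e-07), as were the reads of the whole gene (log2 -6.41). The site itself held 76.4% of the reads of NAC1 over all libraries. Relative to the gene's other reads it differed by a log2 of -0.18 (adjusted p = 0.754, range over its alternatives 9.81e-11 to 0.754). HAM3 cut ends at the miR171b position were 10.1-fold lower (adjusted p = 6.60e-04), but not relative to the gene's other reads (adjusted p = 0.284, range 2.09e-04 to 0.284).

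Cut ends were higher in apices at sites of CUC2, SPL15, HAM1 and TCP4. CUC2, a boundary gene cut through miR164a (chromosome 5, 21902301 to 21902321), had 107 reads in apices and 0 in leaves, at least 44.5-fold higher (adjusted p = 1.66e-04). Its call was lost relative to the gene's other reads (adjusted p = 0.0506, range 1.17e-05 to 0.0506). The miR156a site of SPL15, a promoter of the floral transition, rose 10.3-fold (10.5 ± 5.47 against 0.858 ± 1.28 RPM, adjusted p = 0.0144). This was lost without the flc-3 apex of day 9 (0.0747) or day 11 (0.0627) and relative to the gene's other reads (0.499, range 0.00189 to 0.499). HAM1 did not pass at the miR171b position (log2 0.01 ± 0.43, adjusted p = 0.979), nor did HAM2 (log2 0.39 ± 0.35, adjusted p = 0.367). HAM1 at the miR171a position rose 2.65-fold (adjusted p = 0.0207), lost without the FLC apex (0.0772), the flc-3 apex of day 11 (0.0815) or relative to the gene (0.258, range 0.00104 to 0.258). TCP4, a regulator of leaf growth cut through miR319c, rose 2.66-fold (adjusted p = 0.0338), lost without the FLC apex (0.0725), the flc-3 apex of day 11 (0.194), flc-3 leaf 3 (0.0747), leaf 9 (0.0750) or leaf 11 (0.0618) and relative to the gene (0.578, range 0.0115 to 0.578). In edgeR, 26 of 75 sites passed the threshold, 8 higher and 18 lower in apices, 22 of them in known targets. Relative to the other reads of each gene 18 passed, 2 higher and 16 lower, of which 10 were among these 26. Without the FLC apex 17 passed, and 12 without the flc-3 apex of day 11.

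**Figure D2:**
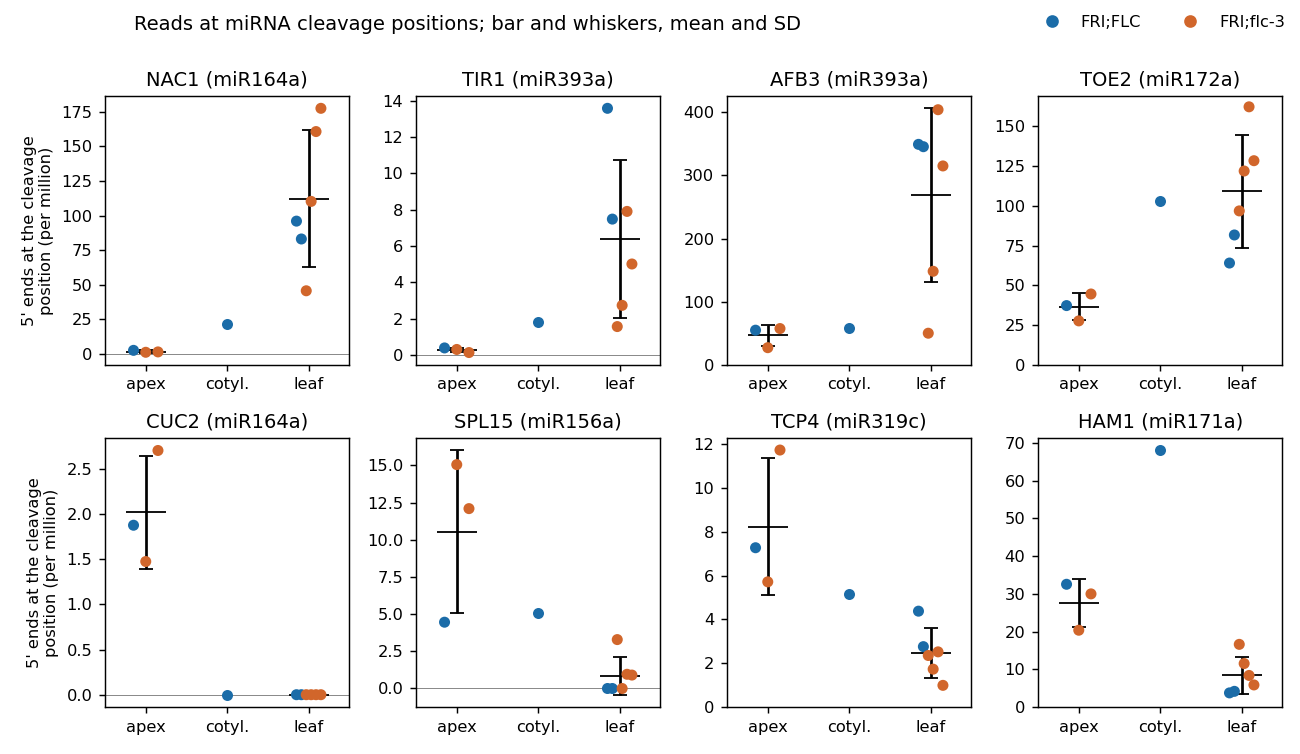
RPM of reads beginning at the expected cut (vertical axis) in apices, cotyledons and leaves at microRNA sites, with a point per library and bars for the mean and SD. TIR1 has a mean of 0.279 in the 3 apices and 6.38 in the 6 leaves, while SPL15 has 10.5 in the apices and 0.858 in the leaves.

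miR156 keeps plants juvenile by cutting SPL transcripts, and miR172 acts later by cutting AP2-like transcripts, so both sums were compared. Cut ends of SPL genes summed to 42.2 ± 15.4 RPM in apices (SD, n = 3) and 45.7 ± 21.6 in leaves (n = 6), a difference within the spread between libraries (exact two-sided permutation p = 0.869). This sum joined sites that moved in opposite ways, with the miR156a site of SPL15 higher and the miR157a site of SPL11 lower in apices. Cut ends of AP2-like genes summed to 47.5 ± 11.6 and 145 ± 50.9, 2.97-fold lower in apices (exact p = 0.0119, the smallest that 84 splits can give, adjusted p = 0.0357 over 3 measures). TOE2 supplied 12624 of the 16282 AP2-like reads over the 10 libraries, so this sum largely repeats the result of TOE2. The apices also came from younger plants than the leaves, so organ and age cannot be told apart here. The ratio of miR172 to miR156 cut ends was 1.19 ± 0.335 in apices and 3.51 ± 1.15 in leaves, 2.83-fold lower (exact p = 0.0238, adjusted p = 0.0357). This ratio no longer passed without the flc-3 apex of day 9 or of day 11 (exact p = 0.0714 for each) or without FLC leaf 11 or flc-3 leaf 3, 9 or 11 (0.0536 for each). Late against early leaves had an exact p of 0.467 for SPL genes, 0.667 for AP2-like genes and 0.20 for the ratio, in a design of 4 against 2 libraries that cannot go below 0.0667.

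**Figure D3:**
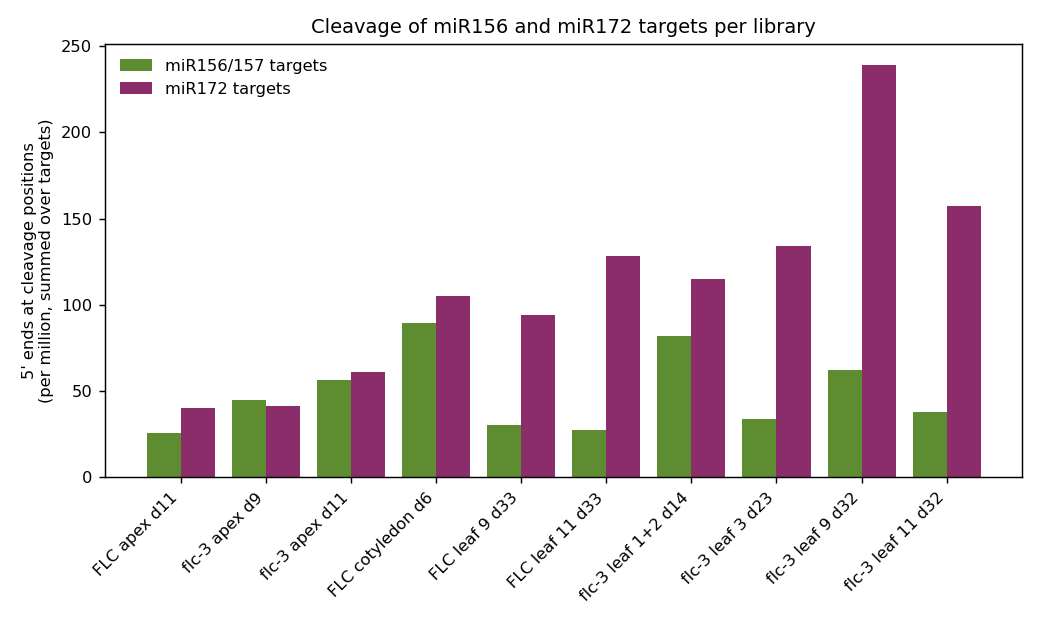
Reads at the miR156 and miR157 sites of SPL genes and at the miR172 sites of AP2-like genes, summed as RPM (vertical axis), in each of the 10 libraries (horizontal axis), a bar per sum and library. The AP2-like sum lies between 40.2 and 60.8 in the 3 apices and between 94.0 and 239 in the 6 leaves.

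Whole genes were compared between the same apices and leaves. PDF1, expressed in the outermost cell layer of the shoot (AT2G42840, chromosome 2, 17826071 to 17827648), stood at 1296 ± 143 CPM in apices and 0.839 ± 0.546 in leaves (SD, n = 3 and 6), a log2 change of 10.74 ± 0.48 (SE, adjusted p = 4.56e-07). KNAT1, a homeobox gene of the meristem (chromosome 4, 5147699 to 5151159), stood at 13.3 ± 3.67 and 0.176 ± 0.239 CPM, a log2 change of 6.03 ± 0.63 (adjusted p = 3.61e-05). LURP1, a gene induced in defence (AT2G14560, chromosome 2, 6213617 to 6215932), stood at 0.399 ± 0.0641 CPM in apices and 385 ± 200 in leaves (945-fold, adjusted p = 4.28e-06). NAP, a NAC regulator of leaf senescence (chromosome 1, 26122080 to 26123514), stood at 0.471 ± 0.119 and 27.8 ± 17.6 (59.8-fold, adjusted p = 4.67e-05). In all, 9 of 13 lists passed with the preset correlation (5 higher and 4 lower in apices) and 0 with an estimated correlation. With edgeR, 10197 of 18574 genes passed the threshold, 4931 higher and 5266 lower in apices.

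Among the largest increases in apices, 3 lipid-transfer protein genes lay together on chromosome 4: AT4G22485 (11844506 to 11846476, log2 11.24 ± 0.78), AT4G22505 (11851155 to 11853018, log2 10.84 ± 0.70, 5142 ± 3377 CPM in apices) and AT4G22490 (11849653 to 11850436, 4721-fold by counts, interval 1306 to 38990). AT1G31310, annotated as a hydroxyproline-rich glycoprotein (chromosome 1, 11198353 to 11200141), had no read in leaves and was at least 841-fold higher in apices. The fatty acid desaturase AT1G06360 (chromosome 1, 1938862 to 1940496, log2 11.15 ± 0.54), the putative membrane lipoprotein AT4G29030 (chromosome 4, 14307195 to 14308022, log2 11.07 ± 0.44) and the cytochrome P450 CYP77B1 (chromosome 1, 3901950 to 3903895, log2 10.89 ± 0.44) completed this group. Lowest in apices relative to leaves were ZAT7, a stress-induced zinc finger gene (chromosome 3, 16925881 to 16926883), with no read in apices and at least 312-fold lower, and the uncharacterized AT1G64360 (chromosome 1, 23887809 to 23888615, log2 -10.54 ± 1.43). They were followed by the calmodulin-like CML41 (chromosome 3, 18873911 to 18874836, 0.428 ± 0.261 CPM in apices and 597 ± 903 in leaves, of which flc-3 leaf 11 had 2336, log2 -10.37, adjusted p = 0.00523, and log2 -9.11 without that leaf), PCR1 (chromosome 1, 5132506 to 5133860, log2 -10.23 ± 1.09) and FUT4, a fucosyltransferase of cell wall proteins (chromosome 2, 6709116 to 6711156, log2 -9.60 ± 1.03). The calcium-binding AT3G01830 (chromosome 3, 296024 to 299263) was 1519-fold lower by counts (interval 420 to 12550) and the ankyrin repeat gene AT5G15500 (chromosome 5, 5031648 to 5033540) 1080-fold (interval 369 to 5238).

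All 22 cell cycle and DNA replication genes rose in apices, also when adjusted over the list alone (camera adjusted p = 2.10e-11, and adjusted p = 0.220 with an estimated correlation). CYCA1;1, a mitotic cyclin, went from 0.948 ± 0.336 CPM in leaves to 40.2 ± 3.15 in apices, the cytokinesis kinesin HINKEL rose 57.4-fold, and the cyclin CYCB2;1 rose 273-fold by counts (interval 93.1 to 1329). Of 28 tested cytosolic ribosomal protein genes 22 rose and 1 fell (24 and 1 adjusted over the list alone, adjusted p = 3.95e-08, and adjusted p = 0.227 with an estimated correlation), among them RPL5B (5.56-fold) and RPS13A (4.31-fold). Meristem and boundary regulators rose for 12 of 13 tested members (12 higher and 1 lower adjusted over the list alone, adjusted p = 2.92e-06, and adjusted p = 0.114 with an estimated correlation), with KNAT6 15.4-fold and the boundary gene CUC3 33.9-fold higher.

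Genes of light harvesting and the photosystems fell in apices for 39 of 46 members and rose for 1 (40 and 1 adjusted over the list alone, adjusted p = 4.76e-10, and adjusted p = 0.227 with an estimated correlation). The photosystem II protein PSBW fell 3.69-fold, and LHCB2.1, an antenna protein, fell 7.84-fold. Of 10 Rubisco and Calvin cycle genes 7 fell (7 adjusted over the list alone, adjusted p = 0.00241, and adjusted p = 0.324 with an estimated correlation), including the regulator CP12-2 (14.0-fold) and Rubisco activase RCA (6.19-fold). Salicylic acid and defence genes fell for 7 of 8 members (7 adjusted over the list alone, adjusted p = 7.92e-04, and adjusted p = 0.227 with an estimated correlation), among them the pathogenesis-related gene PR5 (10.7-fold) and the defence regulator WRKY70 (8.85-fold). All 11 tested senescence genes fell (11 adjusted over the list alone, adjusted p = 5.00e-04, and adjusted p = 0.227 with an estimated correlation), with the regulators WRKY53 29.4-fold and ORE1 42.2-fold lower. Calls of lists were lost with an estimated correlation in every comparison and held only with the preset value.

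Marker genes of other cell types moved with these groups. Of 7 trichome and epidermis genes 6 rose in apices and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.00116, and adjusted p = 0.114 with an estimated correlation), with the trichome regulators GL2 16.1-fold and GL1 1017-fold by counts (interval 182 to 40220) higher. The early stomatal genes SPCH (882-fold by counts, interval 244 to 7292), TMM (34.0-fold) and EPF2 (at least 170-fold) rose. FAMA, which acts later in the stomatal lineage, stood at 13.6 ± 3.26 CPM in apices and 20.0 ± 3.98 in leaves (adjusted p = 0.0594). The stomatal list thus had 3 of 4 members higher (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.00794, and adjusted p = 0.227 with an estimated correlation). Its direction turned without the FLC apex (adjusted p = 0.689), the flc-3 apex of day 9 (0.456) or of day 11 (0.535). The range over its alternatives was 0.00668 to 0.689. Without any of these apices only FAMA was left to test. SPCH, TMM and EPF2 reached 1 CPM in 3 apex and 0 leaf libraries, so they were tested only because apices were high. The filter thus set their direction and that of the list. Among vascular genes, the phloem genes SUC2 (13.5-fold) and APL (3.69-fold) fell, the xylem gene IRX3 rose 3.12-fold, and ATHB8 rose by a log2 of 0.80 ± 0.31 (adjusted p = 0.0495, lost in 10 of 16 alternatives, range 0.0277 to 0.174). Their list did not pass (2 higher and 2 lower, also adjusted over the list alone, adjusted p = 0.452). SEP1, the only tested floral organ gene, fell by 6.72 ± 2.35 on the log2 scale (adjusted p = 0.0316), lost in 5 alternatives (range 0.00309 to 0.108), among them without the FLC apex (0.104) and without the flc-3 apex of day 9 (0.108) or day 11 (0.0750). Among leaves SEP1 stood apart in flc-3 leaf 11, at 81.6 CPM. The floral list did not pass (1 lower, also adjusted over the list alone, adjusted p = 0.552).

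Flowering time genes went both ways, with 2 of 18 higher and 6 lower in apices (the same counts adjusted over the list alone, adjusted p = 0.533). The clock gene GI fell 2.14-fold, the repressor SVP 2.40-fold and SPL3 2.41-fold, while MAF4, a relative of FLC, rose 2.13-fold. FLC itself differed by a log2 of 0.12 ± 1.02 (adjusted p = 0.927). Small RNA and RNA decay genes rose for 5 of 15 members and fell for 1 (the same adjusted over the list alone, adjusted p = 0.166). SE, HEN1 and AGO1, which make, methylate and use microRNAs, rose 2.31-fold, 1.94-fold and 1.72-fold, and the exonuclease XRN2 rose 1.55-fold (adjusted p = 0.0241), lost without the flc-3 apex of day 9 (0.0937) or day 11 (0.0540) or flc-3 leaf 3 (0.0566, range 0.00996 to 0.0937).

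The next comparison asked what differed between FLC and flc-3 plants in pairs matched by organ and leaf number. Leaf 11 was a rosette leaf in FLC and a cauline leaf in flc-3 plants, so that pair differed in leaf type too. SOC1, FUL and SWEET15 had more RNA ends in flc-3 plants, and RAV2, a repressor of FT also known as TEM2, had almost none. RAV2 (AT1G68840, chromosome 1, 25880155 to 25882222) stood at 0.305, 1.58 and 1.41 CPM in the apex, leaf 9 and leaf 11 of flc-3 plants and at 16.7, 163 and 181 in those of FLC plants. It was 96.0-fold lower in flc-3 (log2 -6.58 ± 0.36 SE, n = 3 each, edgeR adjusted p = 2.69e-04). SOC1, a MADS-box integrator of flowering signals (chromosome 2, 18807505 to 18811125), rose 21.9-fold (37.7 ± 28.3 against 1.74 ± 1.34 CPM, SD, adjusted p = 0.00509). FUL, a MADS-box gene of the floral transition (chromosome 5, 24502434 to 24506269), rose 15.2-fold (adjusted p = 0.0341), with 57.6 CPM in flc-3 leaf 11, the cauline leaf. SWEET15, a sugar exporter also called SAG29 (chromosome 5, 4181042 to 4183354), rose 96.4-fold (adjusted p = 0.0183), with 90.4 and 148 CPM in flc-3 leaves 9 and 11 against 0.716 and 1.40 in FLC leaves 9 and 11, while the flc-3 and FLC apices of day 11 had 0.0762 and 0.0644. These apex values lie under the floors of 0.114 and 0.193 CPM and cannot be told from 0, so the rise rests on the leaves. FLC was 8.86-fold lower in flc-3 (9.26 ± 3.61 against 77.4 ± 2.27 CPM, adjusted p = 0.0176). FT, which carries the flowering signal from leaves, had no read in FLC leaves 9 and 11, whose floors are 0.358 and 0.699 CPM, and 32.6 and 164 CPM in flc-3 leaves 9 and 11. FT was chosen after its values were seen.

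**Figure D4:**
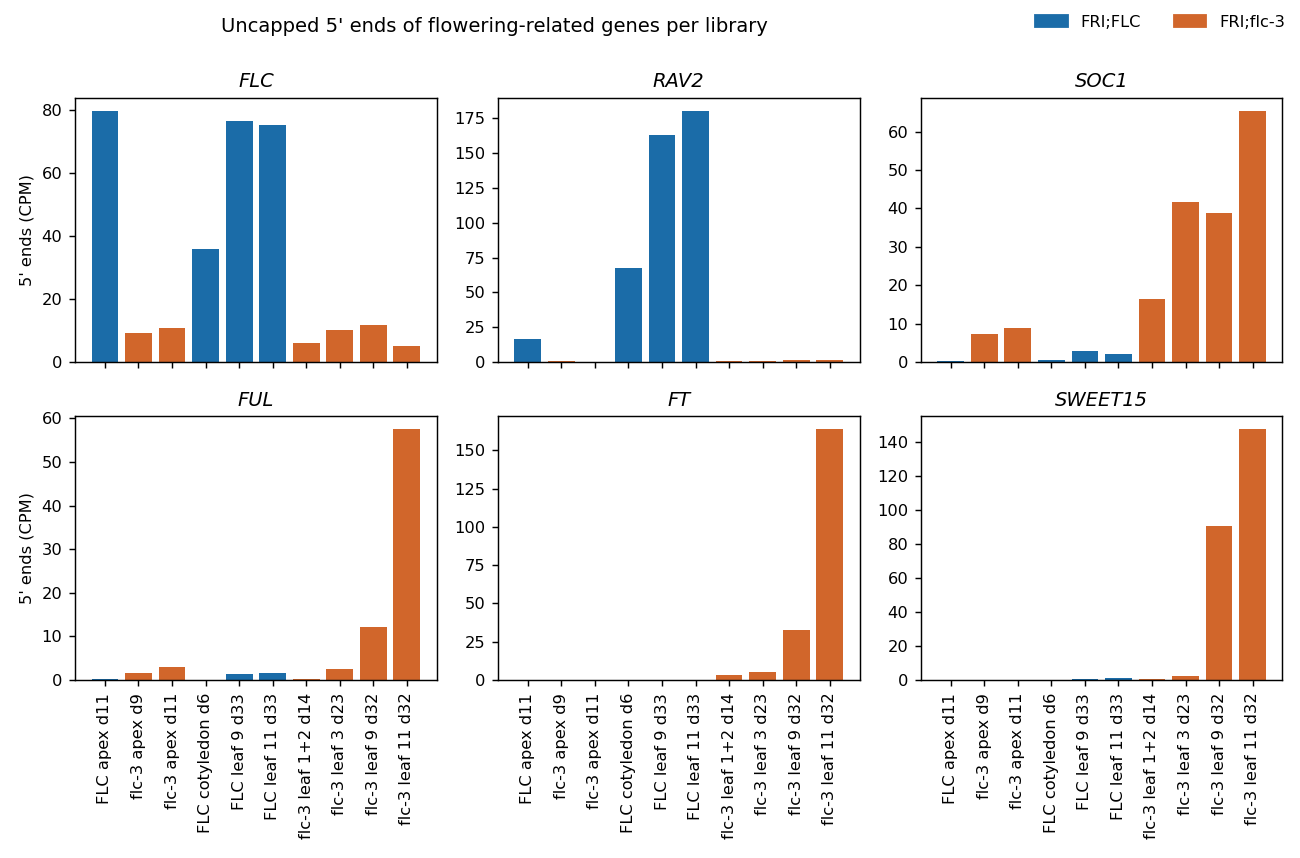
CPM (vertical axis) of FLC, RAV2, SOC1, FUL, FT and SWEET15 in each of the 10 libraries (horizontal axis), a bar per library coloured by genotype. FLC lies between 35.9 and 79.9 in the 4 FLC libraries and between 5.14 and 11.8 in the 6 flc-3 libraries, and RAV2 between 16.7 and 181 and between 0.305 and 1.58.

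In edgeR, 7 of 17366 genes passed the threshold, 3 higher and 4 lower in flc-3, and 1882 had an unadjusted p under 0.05. The remaining calls were AT2G07080, an uncharacterized gene (chromosome 2, 2936239 to 2938827, log2 -3.12 ± 0.35, adjusted p = 0.0242), and AT5G61160 (log2 -3.64), which lies below the expression limit for named genes and was chosen after its values were seen. The calls rest on 2 residual degrees of freedom. DESeq2 called 229 genes and edgeR 68 without a filter on low counts, 4 without the highest position of each gene, 3013 without the apex pair and 3 without the leaf 9 pair. Without the leaf 9 pair the calls of FLC (adjusted p = 0.0703, range 2.70e-16 to 0.0703) and AT2G07080 (0.164, range 3.36e-11 to 0.164) were lost. FUL lost its call without the leaf 11 pair (0.219), without the pair block (0.203), with all 10 libraries (0.216) and without its highest position (0.0594, range 9.94e-10 to 0.219).

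Between genotypes 2 of 12 lists passed, and 0 with an estimated correlation. Cell cycle genes were lower in flc-3 plants as a list (camera adjusted p = 3.31e-05, and adjusted p = 0.746 with an estimated correlation), and so were cytosolic ribosomal protein genes (adjusted p = 9.67e-04, and adjusted p = 0.746 with an estimated correlation). No single member of either passed in edgeR, also when adjusted over the list alone, with 6 of 15 and 6 of 28 at an unadjusted p under 0.05 and 1 and 0 by DESeq2. MCM2, a DNA replication helicase subunit, had a log2 change of -1.50 ± 0.52 (adjusted p = 0.454) and RPL18 of -1.38 ± 0.47 (adjusted p = 0.454). In the apex pair alone these log2 changes were 0.09 and -0.13, against -2.29 and -2.02 in the leaf pairs. The flowering time list had 2 of 17 members higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.155), and it passed without the leaf 9 pair (0.0409) or the leaf 11 pair (8.13e-04, range 8.13e-04 to 0.746). SPL4, a target of miR156, had 12.0 ± 13.1 CPM in flc-3 against 2.60 ± 2.26 (adjusted p = 0.182). Senescence genes had 1 of 11 higher, SWEET15 (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.536). SAG21 and SAG13 had log2 changes of -1.78 ± 0.38 and 1.43 ± 0.41 (adjusted p = 0.332 and 0.454).

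The other lists had no member past the threshold in edgeR between genotypes, over all genes or adjusted over the list alone, and none by DESeq2. At an unadjusted p under 0.05 stood 2 of 10 Rubisco and Calvin cycle genes (list adjusted p = 0.120, and 0.0416 without the apex pair, range 0.0416 to 0.746), 0 of 46 light harvesting genes (0.468), 1 of 7 meristem genes (0.468), 1 of 8 defence genes (0.536), 1 of 15 small RNA genes (0.468), 0 of 1 stomatal genes (0.536), 0 of 5 epidermis genes (0.543) and 0 of 4 vascular genes (0.468). CP12-2 had a log2 change of 1.14 ± 0.37 (adjusted p = 0.454) and the defence gene PR1 of -3.20 ± 1.30 (adjusted p = 0.455). No floral organ gene could be tested. Among cleavage sites, edgeR called 0 of 75 between genotypes, with 6 at an unadjusted p under 0.05, and no other tool was run. Closest were the miR157a site of SPL15 (4.71 ± 6.21 against 0.926 ± 1.44 RPM) and the miR168a site of AGO1 (6.67 ± 2.39 against 3.08 ± 4.73, adjusted p = 0.0773 for both). AGO1 passed without the apex pair (0.0381), and TOE1 passed relative to its other reads (log2 2.21, adjusted p = 0.0203).

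Late leaves (9 and 11, 4 libraries) were compared with early leaves (1 and 2, and 3, 2 libraries). With genotype as a covariate the folds rest on flc-3 leaves, 2 late against 2 early, and FLC leaves 9 and 11 bear only on the spread. SWEET15 rose 65.3-fold (log2 6.03 ± 0.52 SE, edgeR adjusted p = 0.0120), with 1.63 ± 1.17 CPM in early leaves (SD, n = 2), 90.4 and 148 in flc-3 leaves 9 and 11, but 0.716 and 1.40 in FLC leaves 9 and 11, no higher than in early leaves. The amino acid transporter family members UMAMIT36 (chromosome 1, 26456774 to 26459570, 59.4-fold) and UMAMIT42 (chromosome 5, 16073534 to 16076221, 13.6-fold), the anthocyanin regulator AT1G56650 (chromosome 1, 21233555 to 21235292, 25.6-fold), the acyltransferase AT3G22560 (chromosome 3, 7998625 to 7999552, 34.2-fold) and the drought-induced RD20 (chromosome 2, 14144831 to 14146555, 11.6-fold) rose too. AT2G41380 (14.5-fold), DIP2 (13.6-fold) and AT4G21930 (8.85-fold) were the other large increases. BZIP61 (chromosome 3, 21520974 to 21523518, 28.5-fold), DREB26 (chromosome 1, 7696427 to 7697831, 19.8-fold), AT1G78850 (8.49-fold), AT3G19680 (7.17-fold), AT4G37240 (5.82-fold), sks17 (5.81-fold), AT4G13575 (5.54-fold) and DGR2 (5.45-fold) fell, as did MCM2 (6.22-fold, adjusted p = 0.0300) and the ribonucleotide reductase gene TSO2 (3.67-fold, adjusted p = 0.0489). FLC differed by a log2 of 0.01 ± 0.41 between late and early leaves (adjusted p = 0.991).

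In edgeR, 102 of 17140 genes passed between late and early leaves, 76 higher and 26 lower. Both early libraries came from younger flc-3 plants, so leaf position, plant age and library cannot be separated. No gene passed without FLC leaf 9 or FLC leaf 11 or with flc-3 leaves alone (edgeR, with 2353, 2370 and 2296 at an unadjusted p under 0.05, no other tool run). All 19 calls of the genes named here were lost without FLC leaf 9 (adjusted p 0.117 to 0.188) and without FLC leaf 11 (0.120 to 0.185). The folds hardly moved, because these leaves supply only a residual degree of freedom: without FLC leaf 9 the log2 change was 6.04 for SWEET15, -4.84 for BZIP61 and -2.64 for MCM2, against 6.03, -4.83 and -2.64. Of the same 19, 7 were lost without flc-3 leaves 1 and 2 (0.0552 to 0.205), 1 without leaf 3 (0.0621), 11 without leaf 9 (0.0548 to 0.149) and 10 without leaf 11 (0.0672 to 0.170). Without flc-3 leaves 1 and 2 edgeR called 59 genes (37 higher and 22 lower), without flc-3 leaf 3 it called 1339 (678 and 661), without flc-3 leaf 9 it called 60 (41 and 19) and without flc-3 leaf 11 it called 71 (65 and 6). DESeq2 called 962 (517 higher and 445 lower), edgeR without a filter 1901 (1045 and 856), and leaf number as a numeric term 181 (104 and 77).

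Between late and early leaves 8 of 13 lists passed, 4 without flc-3 leaves 1 and 2 or without flc-3 leaf 11, and 0 with an estimated correlation. Cell cycle genes were lower in late leaves as a list (camera adjusted p = 2.27e-08, and adjusted p = 0.584 with an estimated correlation), with 2 of 11 members past the threshold (8 adjusted over the list alone). Light harvesting genes were lower as a list (adjusted p = 1.17e-04, and adjusted p = 0.596 with an estimated correlation). Cytosolic ribosomal protein genes were too (0.00278, and adjusted p = 0.596 with an estimated correlation, lost without flc-3 leaf 11 at 0.207, range 1.48e-04 to 0.596). Of these, 4 of 46 and 5 of 28 had an unadjusted p under 0.05 in edgeR and none passed there, adjusted over the list alone or by DESeq2. The Rubisco and Calvin cycle list was lower (0.0397, and adjusted p = 0.638 with an estimated correlation, 1 of 10 lower adjusted over the list alone), lost without flc-3 leaves 1 and 2 (0.597) or leaf 9 (0.213, range 0.00217 to 0.638). Senescence genes were higher as a list (9.85e-04, and adjusted p = 0.596 with an estimated correlation, 1 of 11 past the threshold and 3 adjusted over the list alone), lost without flc-3 leaves 1 and 2 (0.180) or leaf 11 (0.0667, range 1.25e-06 to 0.596). The defence list was higher (0.0397, and adjusted p = 0.638 with an estimated correlation), with 1 of 8 at an unadjusted p under 0.05 and lost without flc-3 leaves 1 and 2 (0.473) or leaf 11 (0.218, range 0.0139 to 0.638). The flowering time list was higher (0.0397, and adjusted p = 0.596 with an estimated correlation), with 3 of 18 at an unadjusted p under 0.05, 2 called by DESeq2, and lost without flc-3 leaves 1 and 2 (0.349, range 0.0269 to 0.596). SEP1 alone made up the floral list (0.0348, and adjusted p = 0.584 with an estimated correlation, 1 of 1 adjusted over the list alone). It did not pass in edgeR over all genes, and it stood apart in flc-3 leaf 11, at 81.6 CPM.

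Neither meristem genes (0 of 6 at an unadjusted p under 0.05 in edgeR and none by DESeq2, list adjusted p = 0.635), nor stomatal (0 of 1, 0.324) or vascular genes (0 of 4, 0.788) passed between late and early leaves. Small RNA genes (1 of 15, 0.858) had a median log2 change of -0.03 and a mean of 0.01. Epidermis genes (2 of 4, 0.722) had a median of -0.18 and a mean of 0.10, so that median and mean differed in sign in both lists. At cleavage sites, 3 of 71 passed in edgeR, all higher in late leaves: the miR172c sites of TOE3 (4.58 and 2.14 RPM in flc-3 leaves 9 and 11 and 13.1 and 8.07 in those of FLC plants against 0.643 ± 0.198 in early leaves, 5.42-fold, chromosome 5, 26802175 to 26802195, adjusted p = 0.0297) and TOE1 (3.76-fold, adjusted p = 0.0310) and the miR393a site of AFB3 (353 ± 37.1 in late leaves, 3.70-fold, adjusted p = 0.0310). Relative to the genes' other reads only TOE1 passed (log2 2.24, adjusted p = 0.0166), and AFB3 (0.118) and TOE3 (0.135) were lost. Without FLC leaf 9 only 1 of these calls was left, and without flc-3 leaf 9 none, with 5 sites at an unadjusted p under 0.05. AFB3 lost its call also without FLC leaf 11 (0.118), flc-3 leaf 11 (0.331) and, with TOE3 and TOE1, without flc-3 leaf 9 (0.515, 0.515 and 0.743). TOE3 and TOE1 were lost without flc-3 leaf 3 as well (0.236 and 0.218), where NAC1 (2.70e-04, higher) and 1 other site, lower in late leaves, were gained. AFB3 and TOE1 were lost without FLC leaf 9 (0.173 and 0.122).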

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

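Every test in this part was chosen after the result had been seen, except the test of a lost region around RAV2. In groups of 4 leaf libraries of flc-3 plants or all 6 leaf libraries, 39 of 346 groups of values had 1 library far from the others. Chance gives about 1 in 20 for replicates of 1 condition. That rate does not hold here, because the groups overlap, pool leaves of different position, age and genotype, and include genes named for differing between leaves. Of these values 15 were in flc-3 leaves 1 and 2, 11 in flc-3 leaf 11, 7 in flc-3 leaf 9, 3 in FLC leaf 9, 2 in FLC leaf 11 and 1 in flc-3 leaf 3.

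In flc-3 leaves 1 and 2, the leaf library from the youngest plants, some photosynthesis genes stood above the other leaves. These were PRK (1033 CPM), GAPB (1314), RBCS1B (484), RBCS2B (722) and PSBTN (1309). The lipid transfer gene LTP1 (83.3), BZIP61 (53.2), DREB26 (61.3), AT4G37240 (169), sks17 (33.0) and the ribosomal RPL24A (82.4) were high in the same library. Its ratio of miR172 to miR156 cleavage was 1.40, the lowest of the flc-3 leaves. At the miR156a site of SPL15 it had 3.29 RPM and at the miR319c site of TCP24 0.627, the highest of the leaves.

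In flc-3 leaf 11, the cauline leaf, the flowering genes SEP1 (81.6 CPM), FUL (57.6), SPL4 (27) and FT (164) stood above the other leaves. The senescence genes NAP (61.8), SAG13 (30.7) and PAO (261), the salicylic acid gene ICS1 (69.2) and CML41 (2336) were high there too. In flc-3 leaf 9, GI (199), FD (16.1) and HEN1 (12.9) were the highest of their groups. Values that rest on 1 or 2 reads set SPCH apart in flc-3 leaf 11 (0.0856 CPM, floor 0.128) and KNAT2 and GL1 in flc-3 leaf 9 (0.0528 CPM each, floor 0.158). They lie under the floor of 3 counts and cannot be told from 0. FLC leaf 9 stood apart for ANT (5.61 CPM), the miR172e site of SNZ (1.203 RPM) and its 9.35% of unplaced reads. FLC leaf 11 stood apart for AT4G22485 (2.33 CPM) and PR1 (177 CPM). No read at the miR161.2 site of AT1G63150 (0 RPM) set flc-3 leaf 3 below the other flc-3 leaves.

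In cotyledons, which were used only in alternatives, reads at SPL sites summed to 89.3 and at AP2-like sites to 105 RPM. In a model of the 3 pairs, 23 genes had a genotype difference in leaves that differed from that in the apex, with 1 residual degree of freedom. A model of the 9 apex and leaf libraries called 0 of 18574 (edgeR, with 2566 at an unadjusted p under 0.05, no other tool run).

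RAV2 was near 0 in all 6 flc-3 libraries, apices and leaves alike, and was the only 1 of 10249 genes searched that lay under 0.1 of the lowest FLC library in each of them. Loss of the surrounding chromosome region is argued against by 8 expressed neighbours within 50 kb, the lowest of which had 0.696 of its FLC level. Too few reads are argued against by the 103 reads expected at the lowest FLC level in the shallowest flc-3 library. Loss of RAV2 alone cannot be told apart from low expression, because the 96 reads at 58 positions (0.863% of the FLC level) could be RNA or reads assigned to the wrong library. An effect of FLC on RAV2 and any other difference between the lines stay open and were not tested.

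At HAM1, HAM2 and HAM3, the share of reads at the miR171b position over both positions was 88.3 ± 0.994% in late leaves (SD, n = 4), 70.2 ± 7.20% in early leaves (n = 2), 67.2 ± 0.989% in apices (n = 3) and 41.2% in cotyledons. Late against early leaves gave an exact p of 0.0667, the smallest possible, and an adjusted p of 0.143 over 18 such tests. At 28 sites of other families, at most 1.08% of their summed reads began 3 bases away in any library. These sites had been kept only where the expected position was the highest within 50 bases in at least 2 libraries. A low share was thus partly built in, and a general shift of 5′ ends by 3 bases stays open. A change in which HAM gene supplies the reads is argued against by HAM1 alone, with 35.1 percentage points between late and early leaves. As a hypothesis, the amounts of miR171a and miR171b may differ with leaf position, but small RNAs were not analysed here.

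At SPL genes, the share of reads at the miR157 position, 1 base from that of miR156, was 35.3 ± 2.32% in apices (SD, n = 3), 54.5 ± 16.7% in leaves (n = 6) and 19.9% in cotyledons. The exact p of apices against leaves was 0.0952 (adjusted p = 0.156 over 18 tests), so the pattern did not pass. At 28 sites of other families, at most 2.32% of their summed reads began 1 base away in any library. These sites had been kept only where the expected position was the highest nearby, so a low share was partly built in. A general shift of 5′ ends by 1 base therefore stays open. Whether the amounts of miR156 and miR157 may differ between organs stays open, because small RNAs were not analysed here.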

How the results depend on the processing

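Reads without a mismatch and codon shares without the first and last 15 codons were added after the data had been seen, and all other alternatives were planned. Of the named genes' results, 933 of the values that leave out a library or pair and 1204 of the others kept direction and side of the threshold, 83 and 42 lost a call and 35 and 37 gained it. For named sites 463 and 241 kept both, 40 and 14 lost a call and 4 and 2 gained it. The 10197 genes between apices and leaves stayed within 1.5 times under every alternative. Of 20 simulated 4-fold site changes, 14 were recovered between organs, 4 between genotypes and 2 between leaf positions. No paired analysis was possible by replicate number, because these numbers only count samples within a group. The genotype comparison was paired by organ and leaf number instead.

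Between genotypes, where 7 genes passed, DESeq2 called 229, no filter on low counts 68, leaving out each gene's highest position 4, and leaving out 1 pair 3 to 3013. Between leaf positions, where 102 passed, DESeq2 called 962, no filter 1901, leaf number as a numeric term 181, flc-3 leaves alone 0, and leaving out 1 library 0 to 1339. The cause was not tested, though fewer samples are part of the construction of the last 2. With an estimated correlation 0 lists passed between organs, 0 between genotypes and 0 between leaf positions, against 9, 2 and 8. Leaving out 1 library gave 4 to 8 lists for leaf position. The stomatal list had adjusted p from 0.00668 to 0.689 when 1 library was left out and turned direction without the FLC apex (0.689) and without the flc-3 apex of day 9 (0.456) or day 11 (0.535), because SPCH, TMM and EPF2 then fell below the filter and FAMA was left alone.

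Of cleavage sites, 48 of 75 were found when 5 libraries were required. Between organs 26 passed, and 12 to 32 when 1 library was left out. Relative to the gene's other reads 1 site passed between genotypes and 1 between leaf positions, against 0 and 3, and leaving out 1 pair or library gave 0 to 1 and 0 to 3. The AGO3 site turned from a log2 of -1.43 to 2.24 relative to its gene (adjusted p = 0.0396). The log2 ratio of miR172 to miR156 between organs ran from -1.75 to -1.34 when 1 library was left out. With each transcript given equal weight, the apex minus leaf difference was -0.0037 for codon position 2 (turned from 0.204), -0.160 for position 3 and -0.818 for the stop codon ratio. It was 0.0649 for position 2 with each position counted at most 10 times and, without the outer 15 codons, -0.111 for position 1, 0.160 for position 2 and -0.0483 for position 3. The stop codon difference ran from -0.691 to -0.440 when 1 library was left out. The causes of these changes were not tested.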

Other observations

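The fit of the leaf pairs alone and the codon and stop codon shares were planned, while the genes named from that fit, the other splits and the values per leaf were chosen after the results had been seen. Leaves 9 and 11 of the 2 genotypes, without the apex pair, gave 3013 calls among 16358 genes in edgeR, against 7 with all pairs, but on 1 residual degree of freedom. All calls in this paragraph rest on that fit. The genotype difference in leaves minus that in the apex was also fitted, on the log2 scale, in a model of the 3 pairs and in a model of the 9 apex and leaf libraries, which called 0 genes. For MCM2 it was -2.37 and -0.47 (adjusted p = 0.0555 and 0.907), for RPL18 -1.87 and -1.93 (0.152 and 0.252), for RPS10B -1.70 and -1.73 (0.114 and 0.244), for SAG21 -1.56 and -1.54 (0.148 and 0.638) and for CP12-2 1.41 and 1.11 (0.176 and 0.374). For SBPASE it was 1.49 in the 9 libraries (0.341). SEN1, a gene of darkened and senescing leaves, was higher in flc-3 leaves (log2 2.92 ± 0.29 SE, adjusted p = 4.45e-04, -0.54 in the apex pair), and SAG21, a stress-induced senescence gene, was lower (-2.28 ± 0.26, adjusted p = 8.02e-04). CML41 (5.36 ± 0.56), RD20 (2.06 ± 0.31) and the Calvin cycle genes CP12-2 (1.60 ± 0.27) and SBPASE (1.28 ± 0.23) were higher in flc-3 leaves. MCM2 (-2.29 ± 0.27), the ribosomal proteins RPL18 (-2.02 ± 0.33) and RPS10B (-1.72 ± 0.25), the defence gene LURP1 (-1.53 ± 0.24) and the miR169 target NF-YA10 (-2.11 ± 0.38) were lower. Of the miR160 targets ARF10 (1.17 ± 0.24) and ARF16 (1.16 ± 0.25) were higher, while ARF17 did not pass (-0.52 ± 0.28, adjusted p = 0.214). Genotype, harvest day and library cannot be separated in these 4 leaves, and leaf 11 was a rosette leaf in FLC and a cauline leaf in flc-3 plants.

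RNA ends along codons were nearly even in all libraries. Codon position 2 held 35.0 ± 0.0602% of ends in apices and 34.8 ± 0.0820% in leaves (SD, n = 3 and 6, exact two-sided permutation p = 0.0119, adjusted p = 0.0238). Position 3 held 32.7 ± 0.0357% and 32.9 ± 0.0820% (exact p = 0.0119, adjusted p = 0.0238), and position 1 held 32.3% in both (exact p = 0.976). The difference at position 2 was gone with each transcript given equal weight (exact p = 0.976) and did not pass with each position counted at most 10 times (0.524). Without the outer 15 codons its exact p was 0.0238, and that of position 1 was 0.0595. Position 3 did not pass with equal weight (exact p = 0.0952) or without the outer 15 codons (0.119). Ends 16 and 17 bases before stop codons, where a terminating ribosome protects RNA from decay, were 1.18 ± 0.0609 times the level around them in apices, 1.77 ± 0.461 times in leaves and 1.39 times in cotyledons (exact p = 0.0714, adjusted p = 0.0952 over 4 measures). Without adjustment, the exact p of this difference was 0.0476 with each transcript given equal weight, 0.0595 with each position counted at most 10 times and 0.0357 without flc-3 leaves 1 and 2, leaf 3 or leaf 11. It was 0.0536 without FLC leaf 9 and 0.107 without any of the other 5 libraries. Among libraries this ratio was highest in FLC leaf 9, at 2.53, and lowest in the flc-3 apex of day 9, at 1.11.

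Other splits of the same 9 libraries into 3 and 6 were tested against that by organ. For genes, 1 of 84 splits, the real one, reached 10197, and the highest other gave 5. For cleavage sites, 1 of 84 reached 26 and the highest other gave 1. Every other split placed apices and leaves together in a group, which by construction widens the spread within groups. Low counts were thus built into those splits, so they cannot exclude chance. For lists, 5 of 84 reached 9 and the highest other also gave 9, so chance cannot be excluded. The 10 splits of the 6 paired libraries are too few for a share under 0.05. There, 1 split reached the 7 genes and the highest other gave 0, 6 reached the 2 lists and the highest other gave 4, and 10 reached the 0 sites and the highest other gave 1.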
